A study of Homo sapiens with 6 samples.

How the data were processed

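RNA of U87, an established human glioblastoma cell line, was sequenced in 6 libraries: 3 libraries labelled EGFR+vIII and 3 labelled EGFR+vIII with a TLR2 knockout. EGFR is the epidermal growth factor receptor, vIII is its constitutively active deletion mutant found in glioblastoma, and TLR2 is a cell surface receptor of innate immunity. Groups were taken from the cell type given in the labels, and the labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The labels state extraction of total RNA with a commercial kit; the library kit, its strandedness, the aligner settings, the counter and the annotation release are not given in the sources used here.

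The analysis started from 1 table of the authors' own comparison, with 1 line per RefSeq transcript accession and no value per library. STAR, DESeq2 and the build hg38 are named in the submitters' processing notes, without versions or settings. Per the file headers, the authors deposited for each accession a base mean, used here as a signal of abundance, which is the mean over libraries of counts divided by size factors. The authors' deposited log2 fold change and its standard error (SE) are on the log2 scale. The fold change was read as knockout over EGFR+vIII, the order in which the deposited table names its groups. The deposited Wald score equals the log2 fold change divided by its SE, with a largest gap of 5.39e-07. The authors' deposited p-value comes from that score, and the deposited adjusted p equals a Benjamini-Hochberg adjustment over the accessions that carry one, with a largest gap of 4.48e-07. The largest SE in the authors' deposited table is 0.38 on the log2 scale even where reads are few, a mark of fold changes drawn towards 0, so that changes of accessions with few reads are understated. An adjusted p that the authors' DESeq2 run left missing was kept missing.

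The table held 67933 accessions, of which 49824 (73.3%) were listed at 0, 18109 had a p-value and 10303 had an adjusted p. The lowest base mean with an adjusted p in the deposited table was 3.11. Accessions were matched to gene symbols and positions with a RefSeq gene table of assembly GRCh38.p14, the same build as hg38, and 98.8% of all accessions matched. The 10303 tested accessions covered 9372 matched genes and 126 accessions without a match. Where a gene had several tested accessions, the accession with the highest base mean stood for the gene. Isoforms of a gene are therefore represented by 1 accession, and few reads are listed for most, though not all, genes with several accessions.

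Depth per library is not stated in the table. The 6 smallest base means above 0 recur across accessions and equal 1 read in 1 library, from which the size factors of the 6 libraries were derived. They ranged from 0.928 to 1.07, a ratio of 1.15, with 3 libraries on each side of the fold change. All 3384 accessions below 4 reads' worth (100%) were sums of whole reads within a tolerance of 1e-06. The base means of the table sum to 11240272 normalized reads, which is the average number of reads assigned to accessions per library. Wilson intervals for shares of genes have a confidence level of 95% and cover counting error only.

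A count test over libraries, chosen before the data were examined for the case of a count per library, could not be run on this table, and the authors' deposited adjusted p under 0.05 was used in its place, as the design allowed for that case. Gene lists were tested with the competitive set test of limma 3.58.1 (cameraPR, preset correlation 0.01, R 4.3.3) on the deposited Wald scores, with Benjamini-Hochberg adjustment over the 26 of 33 lists with at least 5 tested members. The correlation between genes could not be estimated without values per library, and a preset correlation of 0.05 was run as the alternative. The 33 lists were fixed before the data were examined. They held Toll-like receptors and adaptors, NF-kB subunits, regulators and feedback targets, chemokines, inflammatory cytokines and receptors, and interferon-stimulated genes. Further lists held antigen presentation by MHC classes I and II, immune checkpoint and suppressive ligands, EGFR family and ligands, MAPK output and JAK-STAT3 targets. Others held histone methylation enzymes, mesenchymal glioblastoma, neural stem and astrocyte markers, matrix and proteases, angiogenic factors, mitosis, DNA replication and p53 targets. More lists held hypoxia, cholesterol synthesis, unfolded protein response, heat shock, TGF-beta and YAP targets, and Wnt pathway genes and targets. The rest held markers of leucocytes, endothelium, epithelium and neurons, mitochondrial mRNAs, ribosomal proteins and replication-dependent histones.

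Genes named in the text follow a rule also set before the data were examined. It takes 12 fixed genes whatever their values, the 12 largest rises and 12 largest falls among genes past the threshold with a base mean of at least 100, leaving out clone, LOC, LINC, pseudogene and antisense symbols and sex-specific genes, and up to 4 members of each list with the smallest p-values. Genes outside this rule are said to be chosen after their values were seen. Shifts along chromosomes were measured as the median log2 fold change of each gene with 40 neighbours, over 4226 genes with a base mean of at least 100, against 1000 permutations of gene positions. The search was repeated on every other gene (2113 genes), each with 20 neighbours, so that the genes left out could measure any region found, and on all genes with running quartiles in place of medians. Gene families were formed from the letters of the symbols, for 136 families of at least 8 tested genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

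The procedures were tested on simulated data built from the deposited base means and SEs of 9372 genes, with 200 genes changed. For the knockout comparison, 32.8% of 67 genes changed 1.5-fold, 50.7% of 67 genes changed 2-fold and 97% of 66 genes changed 4-fold were called, and 6.98% of calls were false. The set test recovered 3 of 3 planted lists and called 0 others. Simulated genes were drawn independently with the spread of the theory, whereas the deposited Wald scores had a central spread 1.75 times as wide. The simulated false calls of genes and lists therefore hold only for such conditions and may be too few for the real table. The shares of changed genes that were called are limited too. Only 200 of 9372 genes were changed, whereas 2352 genes were called in the real table, and the planted changes were not drawn towards 0. Alternatives were other thresholds, adjustment families and abundance minimums, a test of a change of more than 1.5-fold, an empirical null, other rankings and correlations for the set test, random lists matched on abundance, fold changes relative to neighbouring genes, a correction for gene span and a restriction to genes with 1 accession.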

Results

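The data compared U87 glioblastoma cells carrying EGFR and its vIII mutant, with and without a knockout of TLR2, by RNA sequencing of 3 libraries per group. The values were those of 1 table of the authors' own comparison, whose base means sum to 11240272 normalized reads, with library size factors between 0.928 and 1.07. All fold changes are given as knockout over EGFR+vIII, in the order in which the authors' deposited table names its groups. That order could not be checked from the targeted gene: TLR2 (chromosome 4, 153684280 to 153710637, GRCh38) has 8 accessions in the authors' deposited table, and all 8 are listed at 0. If the order were the opposite, every direction given here would reverse.

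A listing at 0 does not show that a gene was silent in these cells, as 4 genes chosen after their values were seen (GAPDH, TUBB, ACTB and PGK1) illustrate. GAPDH, a glycolytic enzyme made by every cell, has 6 accessions in the authors' deposited table and a highest base mean of 6.19, and TUBB, a tubulin, has 7 accessions that are all at 0. ACTB and PGK1, with 1 accession each, have base means of 146602 and 38390 in the authors' deposited table. Among protein-coding genes of the authors' deposited table, a base mean of at least 100 was reached by 3238 of 7927 genes with 1 accession (40.9%, Wilson 95% interval 39.8 to 41.9) and by 9 of 735 genes with 10 or more accessions (1.22%, interval 0.646 to 2.31). KDM6B, a histone H3K27 demethylase, and RELA, an NF-kB subunit, are also listed at 0 in every accession of the authors' deposited table. EGFR (9 accessions, highest base mean 1.32), MYD88 (7 accessions, 0.698) and NFKB1 (3 accessions, 0.158) have no adjusted p in the authors' deposited table, so whether these genes changed was not detectable.

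**Figure D1:**
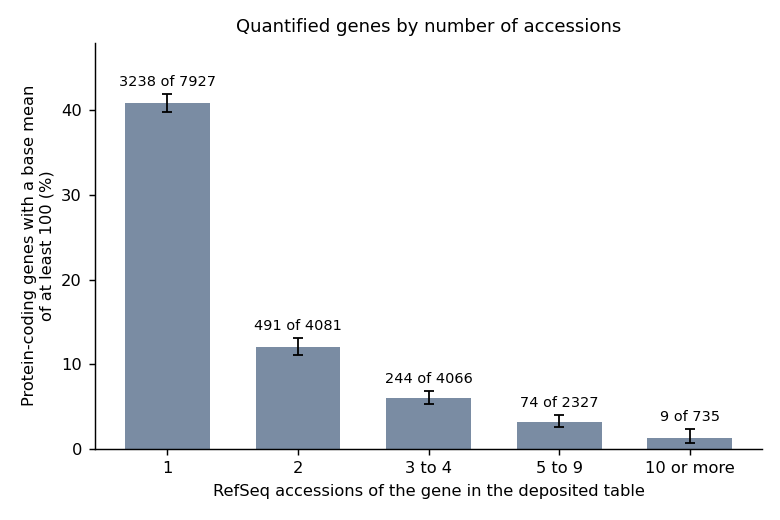
Share of protein-coding genes with a base mean of at least 100 (vertical axis, percent) by the number of RefSeq accessions of the gene in the authors' deposited table (horizontal axis). Bars are shares, lines are Wilson 95% intervals, and the share falls from 40.9% for genes with 1 accession to 1.22% for genes with 10 or more.

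The first question was which genes differed between the knockout and the EGFR+vIII cells. As groups, the lists of NF-kB subunits, regulators and feedback targets, of chemokines and of interferon-stimulated genes were higher in the knockout. Not every member rose: 7 of 12, 8 of 11 and 17 of 24 tested members were called higher, and 1, 0 and 0 lower. The mixed list of collagens, matrix proteins and proteases was lower as a group. DNA replication genes were higher, and hypoxia genes and p53 targets lower, in most but not all settings. In the authors' deposited table, 2417 of 10303 tested accessions (23.5%) had an adjusted p under 0.05, 1191 higher and 1226 lower, and 3311 had an unadjusted p under 0.05. They belonged to 2352 genes, 1159 higher and 1193 lower. Among the called accessions of the authors' deposited table, 341 were at least 2-fold higher and 325 at least 2-fold lower. The median log2 fold change over tested accessions of the authors' deposited table was 0.02, a value set by the authors' scaling. The count depends on the null: 446 accessions passed a test of a change of more than 1.5-fold, and 893 passed when the Wald scores were scaled by their own central spread. Of 123 called genes among those chosen for naming, 42 lost the call with the scaled scores: ALDOC, B2M, CALR, CCL2, CCL8, CSF2, DDB2, HBEGF, HES1, HLA-DPB1, ID2, IRAK2, KRT5, KRT14, LTBP2, NT5E, SOCS3, TGFB1, TIGAR, TLR3, TLR6, TRAF2 and UNC93B1 among those given below. The test of a change of more than 1.5-fold ended the call of 65, those just listed except KRT5 and, below, also CA9, E2F1, E2F2, ENO2, EREG, ERRFI1, ICAM1, KMT2D, MCM5, MCM6, NFKBIA, SOCS1, STC2, THBS1, TLR1 (adjusted p = 0.152) and WNT5A.

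The largest rise in the authors' deposited table was that of G0S2 (chromosome 1, 209675412 to 209676390), an inhibitor of lipolysis, with a log2 fold change of 7.94 (SE 0.28, adjusted p = 8.14e-171). PDZD2, a protein with PDZ domains, rose 63.8-fold (SE 0.28 on the log2 scale) in the authors' deposited table. PDGFRL rose by 5.58 (SE 0.32) and THSD7B by 5.34 (SE 0.25) on the log2 scale of the authors' deposited table. SERPINB3, a protease inhibitor, rose by 5.05 (SE 0.28) in the authors' deposited table, and SERPINB3 has a near-identical paralog with which it can share reads. The other rises were MIR3945HG (4.63), FRMD4B (4.35), FMNL1 (4.09), LRATD2 (3.95), MAGEA1 (3.40), GBP4 (3.40), an interferon-inducible GTPase, and CCDC69 (3.36), each a log2 fold change of the authors' deposited table. MAGEA1, a cancer-testis antigen on chromosome X, also has close paralogs. The adjusted p of these 12 genes in the authors' deposited table was at most 2.16e-52 except for MIR3945HG (3.11e-48) and FRMD4B (4.93e-47).

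The largest fall in the authors' deposited table was that of C11orf87 (chromosome 11, 109422190 to 109429167), with a log2 fold change of -3.62 (SE 0.20, adjusted p = 3.63e-68). GDF6, a bone morphogenetic protein family ligand, fell by 3.58 (SE 0.28) and SEMA3D, a secreted semaphorin, fell by 2.96 (SE 0.27) on the log2 scale of the authors' deposited table. DCC (chromosome 18, 52340197 to 53535899), a netrin receptor, fell by 2.91 (SE 0.11, adjusted p = 1.74e-152) in the authors' deposited table. TOX (-2.86), KCTD16 (-2.80), the ephrin receptor EPHB1 (-2.80), the glutamate transporter SLC1A1 (-2.60), PNMA2 (-2.56), ANXA10 (-2.51) and CYRIA (-2.48) were also lower, by log2 fold changes of the authors' deposited table. MBP, myelin basic protein, has 6 accessions, and the one with the highest base mean had a log2 fold change of -2.71 (SE 0.20) in the authors' deposited table.

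**Figure D2:**
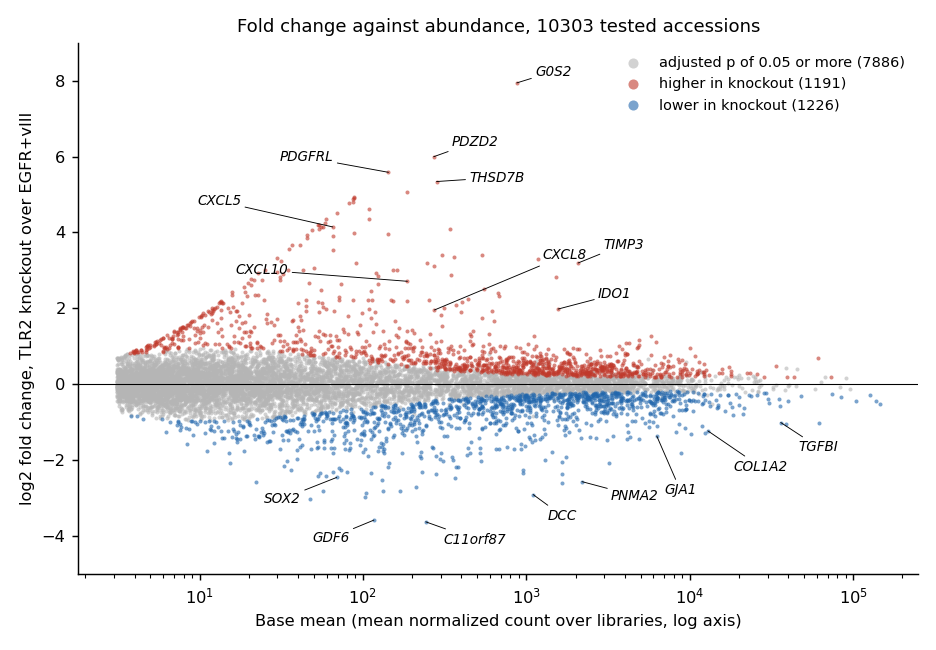
Log2 fold change, knockout over EGFR+vIII (vertical axis), against base mean (horizontal axis, log scale), for the 10303 accessions with an adjusted p in the authors' deposited table. Red points are the 1191 accessions higher and blue points the 1226 lower at an adjusted p under 0.05, and lines join names to points, from G0S2 at 7.94 to C11orf87 at -3.62.

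**Figure D3:**
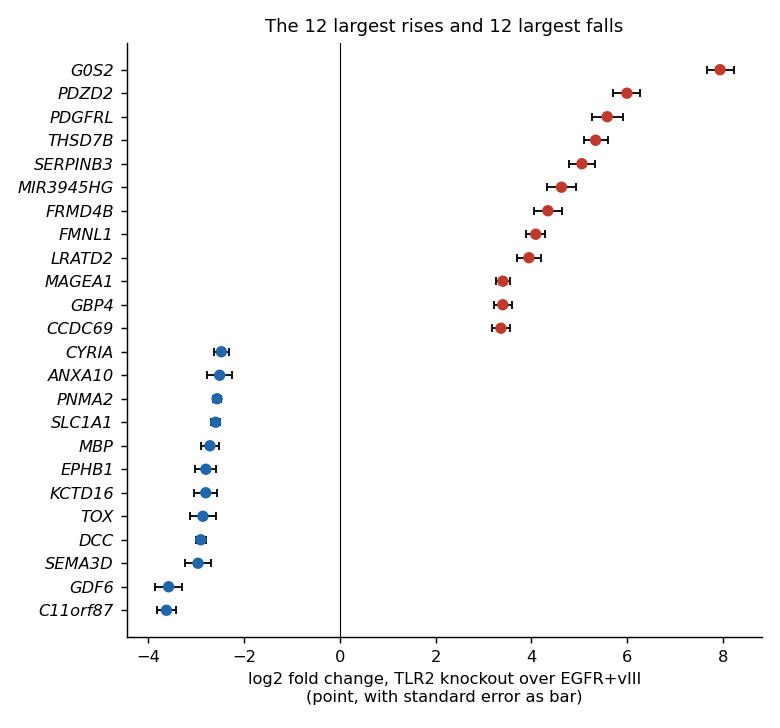
Log2 fold change, knockout over EGFR+vIII (horizontal axis), of the 12 largest rises and 12 largest falls among genes with a base mean of at least 100 in the authors' deposited table. Points are the fold changes and bars are the authors' SE, and every bar is far from 0.

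The next question was which fixed gene lists shifted as a group. Of 26 lists tested, 11 passed the set test at an adjusted p under 0.05, 5 higher and 6 lower in the knockout, and 15 did not pass. Chemokines were higher: 8 of 11 tested members rose and 0 fell in the authors' deposited table (9 and 0 adjusted over the list alone). The adjusted p of the set test was 4.59e-05. CXCL10, a T cell attractant induced by interferon, rose by 2.71 (SE 0.21) and CXCL5, a neutrophil attractant, by 4.15 (SE 0.34) on the log2 scale of the authors' deposited table. CXCL8 rose by 1.96 (SE 0.19, adjusted p = 8.94e-24), CCL2 by 0.92 (SE 0.25, adjusted p = 0.00179) and CCL8 by 1.40 (SE 0.38) in the authors' deposited table. IL6, a cytokine of the same response, had a log2 fold change of -0.51 (SE 0.34, adjusted p = 0.333) in the authors' deposited table. Its base mean was 4.96, close to the lowest tested (3.11), so whether IL6 changed cannot be told from so few reads.

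Interferon-stimulated genes showed the smallest set test p of the lists: 17 of 24 tested members rose and 0 fell in the authors' deposited table (19 and 0 adjusted over the list alone). The set test gave an adjusted p of 2.14e-16. IFITM2 (2.26, SE 0.16), IFITM1 (2.18, SE 0.17), OAS2 (2.09, SE 0.15) and OAS3 (1.09, SE 0.08), antiviral effectors, rose by these log2 fold changes of the authors' deposited table, and IFITM1 and IFITM2 are close paralogs. In the NF-kB list, 7 of 12 tested members rose and 1 fell in the authors' deposited table (8 and 1 adjusted over the list alone). The adjusted p of the set test was 1.11e-05. BIRC3, an inhibitor of apoptosis, rose 8.01-fold (SE 0.23 on the log2 scale) in the authors' deposited table. TNFAIP2 rose by 2.40 (SE 0.12), NFKBIA, the inhibitor that NF-kB induces, by 0.83 (SE 0.09) and TRAF2 by 0.69 (SE 0.15) on the log2 scale of the authors' deposited table.

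Toll-like receptors and adaptors rose in 6 of 8 tested members and fell in 0 in the authors' deposited table (6 and 0 adjusted over the list alone). The set test gave an adjusted p of 0.0284. This call passed in 3 of 8 alternatives. It was lost at a preset correlation of 0.05 (adjusted p = 0.0677), relative to neighbouring genes (0.068), ranked by fold change (0.195), at a base mean of at least 100 (0.062) and against matched random lists (0.0739). TLR1 (0.93, SE 0.14, adjusted p = 1.99e-09) and TLR6 (0.39, SE 0.15, adjusted p = 0.0387), which pair with TLR2 on the cell surface, were higher in the authors' deposited table. Both lie at chromosome 4 positions 38787569 to 38868390, where the median log2 fold change of neighbouring genes in the authors' deposited table was 0.36. Relative to these neighbours, TLR1 kept a log2 fold change of 0.58 (adjusted p = 0.000491) and TLR6 had one of 0.04 (adjusted p = 0.91). UNC93B1, which carries Toll-like receptors to endosomes, rose by 0.72 (SE 0.15), IRAK2 by 0.45 (SE 0.12) and TLR3 by 0.36 (SE 0.13) in the authors' deposited table. TLR4 had a log2 fold change of 0.51 (SE 0.28, adjusted p = 0.198) in the authors' deposited table.

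DNA replication genes rose in 6 of 10 tested members and fell in 0 in the authors' deposited table (6 and 0 adjusted over the list alone). The adjusted p of the set test was 0.000213, and the call was lost when ranked by fold change (adjusted p = 0.171). MCM6 rose by 0.77 (SE 0.07) and MCM5 by 0.62 (SE 0.09), subunits of the replicative helicase, and the transcription factors E2F1 by 0.61 (SE 0.08) and E2F2 by 0.89 (SE 0.15) on the log2 scale of the authors' deposited table. Mitosis genes did not pass (adjusted p = 0.0887), except by ranks of the Wald score (adjusted p = 0.0107), with 4 of 15 tested members higher and 1 lower in the authors' deposited table (6 and 1 adjusted over the list alone).

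Collagens, matrix proteins and proteases were lower as a group: 17 of 31 tested members fell and 3 rose in the authors' deposited table (18 and 4 adjusted over the list alone). The set test gave an adjusted p of 4.2e-08. The protease ADAMTS5 fell by 2.36 (SE 0.11), the proteoglycan LUM fell by 1.71 (SE 0.12) and the collagen chain COL1A2 fell by 1.23 (SE 0.07) on the log2 scale of the authors' deposited table. TIMP3, an inhibitor of matrix proteases, went the other way with a log2 fold change of 3.20 (SE 0.09, adjusted p = 7.64e-266), the smallest p in the authors' deposited table. Mesenchymal glioblastoma markers fell in 8 and rose in 3 of 22 tested members of the authors' deposited table (8 and 5 adjusted over the list alone). Their set test call (adjusted p = 0.0169) passed in 3 of 8 alternatives. It was lost at a preset correlation of 0.05 (adjusted p = 0.0887), ranked by fold change (0.751), by ranks (0.344), at a base mean of at least 100 (0.062) and against matched random lists (0.506). TGFBI (-1.01, SE 0.07) and THBS1 (-0.75, SE 0.07) were lower and CHI3L1, a secreted glycoprotein, was higher (3.01, SE 0.24) in the authors' deposited table.

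Hypoxia genes fell in 6 and rose in 1 of 15 tested members of the authors' deposited table (8 and 1 adjusted over the list alone). The adjusted p of the set test was 0.00319, and this call too was lost when ranked by fold change (adjusted p = 0.195). ADM, a vasodilator peptide, fell by 0.97 (SE 0.09), ENO2, a glycolytic enzyme, fell by 0.75 (SE 0.07), CA9 fell by 0.53 (SE 0.09) and STC2 fell by 0.52 (SE 0.08) on the log2 scale of the authors' deposited table. Targets of p53 fell in 4 and rose in 0 of 13 tested members of the authors' deposited table (5 and 0 adjusted over the list alone). The set test gave an adjusted p of 0.00898, and the call was lost at a base mean of at least 100 (adjusted p = 0.062). GDF15, a stress cytokine, fell by 1.70 (SE 0.13), BTG2 fell by 1.75 (SE 0.21), DDB2 fell by 0.45 (SE 0.11) and TIGAR fell by 0.35 (SE 0.08) on the log2 scale of the authors' deposited table.

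Angiogenic factors fell in 4 and rose in 0 of 8 tested members of the authors' deposited table (4 and 1 adjusted over the list alone). The set test gave an adjusted p of 0.00898 for this list. It was led by THBS2 (-1.45, SE 0.10, in the authors' deposited table) and THBS1, which are known as inhibitors of angiogenesis. This list did not pass when ranked by fold change (adjusted p = 0.195), by ranks of the Wald score (0.169), at a base mean of at least 100 (0.062) or against matched random lists (0.485). Targets of TGF-beta and YAP fell in 5 and rose in 1 of 12 tested members of the authors' deposited table (5 and 2 adjusted over the list alone). Their set test call (adjusted p = 0.0403) passed in 2 of 8 alternatives, relative to neighbouring genes (0.0141) and corrected for gene span (0.017), and the adjusted p of the others was 0.0836 to 0.251. ID3, an inhibitor of differentiation, fell by 1.24 (SE 0.11) and LTBP2 fell by 0.41 (SE 0.11), and ID2 rose by 0.62 (SE 0.17) on the log2 scale of the authors' deposited table.

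**Figure D4:**
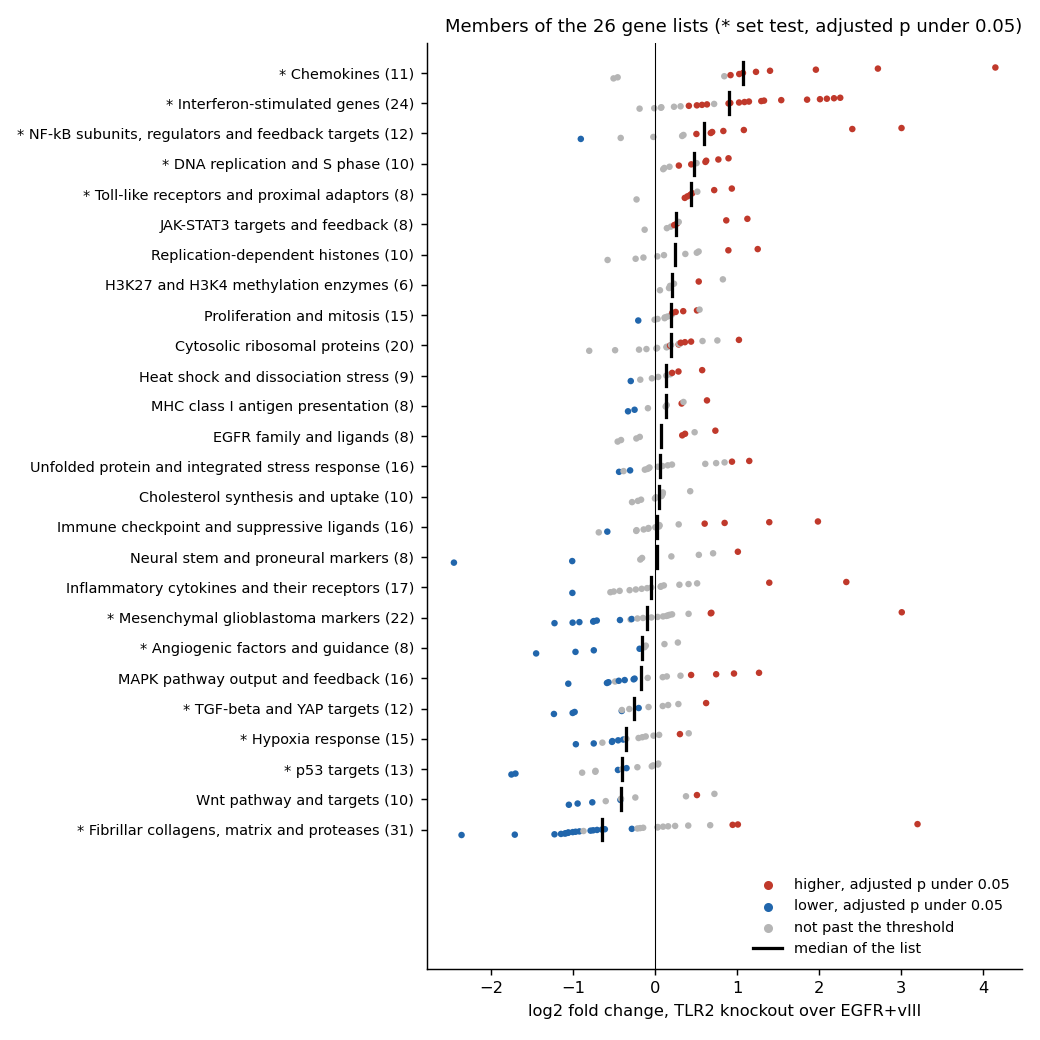
Log2 fold change, knockout over EGFR+vIII (horizontal axis), of the tested members of 26 gene lists, with the number tested in brackets. Points are genes of the authors' deposited table, red if higher, blue if lower and grey if not past an adjusted p of 0.05, black lines are list medians, and stars mark the 11 lists that passed the set test.

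Among the 15 lists that did not pass, immune checkpoint and suppressive ligands had 4 of 16 tested members higher and 1 lower in the authors' deposited table (set test adjusted p = 0.114). IDO1, a tryptophan-degrading enzyme, rose by 1.98 (SE 0.10), ICAM1 by 0.85 (SE 0.11) and NT5E by 0.60 (SE 0.14), and TGFB1 fell by 0.58 (SE 0.13) on the log2 scale of the authors' deposited table. EGFR ligands and family members had 3 of 8 tested members higher and 0 lower in the authors' deposited table (adjusted p = 0.145), with EREG, an EGFR ligand, up by 0.73 (SE 0.07), the EGFR inhibitor ERRFI1 by 0.36 (SE 0.07) and HBEGF by 0.33 (SE 0.10). MAPK output genes went both ways, 4 of 16 higher and 7 lower in the authors' deposited table (adjusted p = 0.264), with the phosphatase DUSP5 up by 0.96 (SE 0.11) and its relative DUSP4 lower at -1.06 (SE 0.12). JAK-STAT3 targets had 4 of 8 tested members higher and 0 lower in the authors' deposited table (adjusted p = 0.104, and 0.0415 by ranks of the Wald score), with the feedback inhibitors SOCS1 up by 1.12 (SE 0.22) and SOCS3 by 0.27 (SE 0.09).

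Inflammatory cytokines and receptors had 2 of 17 tested members higher and 1 lower in the authors' deposited table (adjusted p = 0.278, and 0.0184 among genes with 1 accession, where the median was 0.41), and their median (-0.05) and mean (0.11) log2 fold changes differ in sign. TNFRSF1B, a receptor of tumour necrosis factor, rose by 2.33 (SE 0.12) and CSF2 by 1.39 (SE 0.38) on the log2 scale of the authors' deposited table. Neural stem markers had 1 of 8 tested members higher and 2 lower in the authors' deposited table (adjusted p = 0.945), with a median of 0.02 and a mean of -0.17 on the log2 scale. SOX2, a transcription factor of neural stem cells, was lower (-2.45, SE 0.31), as was HES1 (-1.01, SE 0.21), and NES, the filament protein nestin, was higher (1.01, SE 0.12) in the authors' deposited table. The list of Wnt pathway genes and targets had 1 of 10 tested members higher and 4 lower in the authors' deposited table. The set test adjusted p was 0.145, and that against matched random lists was 0.039. The 4 lower members were Wnt receptors and the ligand WNT5A (-1.05, SE 0.21). The count therefore does not show a fall of Wnt target genes.

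Antigen presentation by MHC class I had 2 of 8 tested members higher and 2 lower in the authors' deposited table (adjusted p = 0.938). B2M was up by 0.32 (SE 0.10) and CALR was at -0.25 (SE 0.07) in the authors' deposited table. Histone methylation enzymes (1 of 6 higher and 0 lower, adjusted p = 0.143), ribosomal proteins (6 of 20 and 0, adjusted p = 0.143), replication-dependent histones (2 of 10 and 0, adjusted p = 0.407), heat shock genes (3 of 9 and 1, adjusted p = 0.487), unfolded protein response genes (2 of 16 and 2, adjusted p = 0.439) and cholesterol synthesis genes (0 of 10 and 0, adjusted p = 0.976) did not pass, with these counts in the authors' deposited table. By ranks of the Wald score, histone methylation enzymes (adjusted p = 0.0347) and ribosomal proteins (0.0415) passed. KMT2D (0.53, SE 0.08), H1-2 (1.25, SE 0.21) and the cystine transporter SLC7A11 (0.94, SE 0.09) were higher in the authors' deposited table. Histone genes have near-identical copies whose reads may be split.

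Of the lists too small to test, the MHC class II list had 3 of 4 tested members higher in the authors' deposited table. They were HLA-DRB5 (1.94, SE 0.12), HLA-DQA1 (2.22, SE 0.29) and HLA-DPB1 (0.95, SE 0.21). CTSS, a protease, did not pass (0.10, adjusted p = 0.766). The other 8 of the 12 members were not tested, 5 of them at 0, so a change of class II genes as a group cannot be told. The 3 higher HLA genes lie on chromosome 6 where the median log2 fold change of neighbouring genes in the authors' deposited table was 0.29 to 0.31. HLA genes also share reads with close paralogs. Both tested astrocyte markers were lower in the authors' deposited table, the gap junction protein GJA1 at -1.37 (SE 0.08) and ALDOC at -0.42 (SE 0.11). Of 3 tested leucocyte markers, LAPTM5 was higher (3.92, SE 0.33) in the authors' deposited table, and CD68 (-0.68, SE 0.32, adjusted p = 0.113) and FCER1G (0.33, SE 0.37, adjusted p = 0.62) did not pass. Of 4 tested epithelial markers, the keratins KRT5 (1.83, SE 0.38) and KRT14 (1.39, SE 0.37) were higher at base means of 10.3 and 7.01 in the authors' deposited table. EPCAM (-0.22, adjusted p = 0.758) and CLDN4 (0.30, adjusted p = 0.664) did not pass. Among endothelial markers 0 of 2 passed and among neuronal markers 0 of 3, and mitochondrial mRNAs had 0 accessions.

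Fold changes were also compared along the chromosomes, with 41-gene medians of the authors' deposited table set against permuted gene positions. In 6 regions some of these running medians passed the limit of 95% of permutations (a shift of 0.311), 4 higher and 2 lower in the knockout, and the largest shift of 0.43 had a permutation p of 0.002. Medians over a whole region, its edges included, are smaller. In the authors' deposited table, genes were higher on chromosome 4 from 439988 to 70690551 (median 0.23), chromosome 6 from 1609915 to 42087462 (0.29), chromosome 11 from 46677080 to 66568606 (0.29) and chromosome 20 from 35772015 to 59940305 (0.23). They were lower on chromosome 8 from 208344 to 63038806 (-0.34) and on chromosome 18 from 2916994 to 62586729 (-0.28) in the authors' deposited table. Chromosomes without a region could lean as well. The medians furthest from 0 among them were those of X (-0.17, 12 genes called higher and 54 lower of 149) and 3 (-0.14, 22 and 85 of 236). Of the 10 genes with a base mean of at least 100 within 10 Mb of TLR2, 1 was called in the authors' deposited table, and their median log2 fold change was 0.06.

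**Figure D5:**
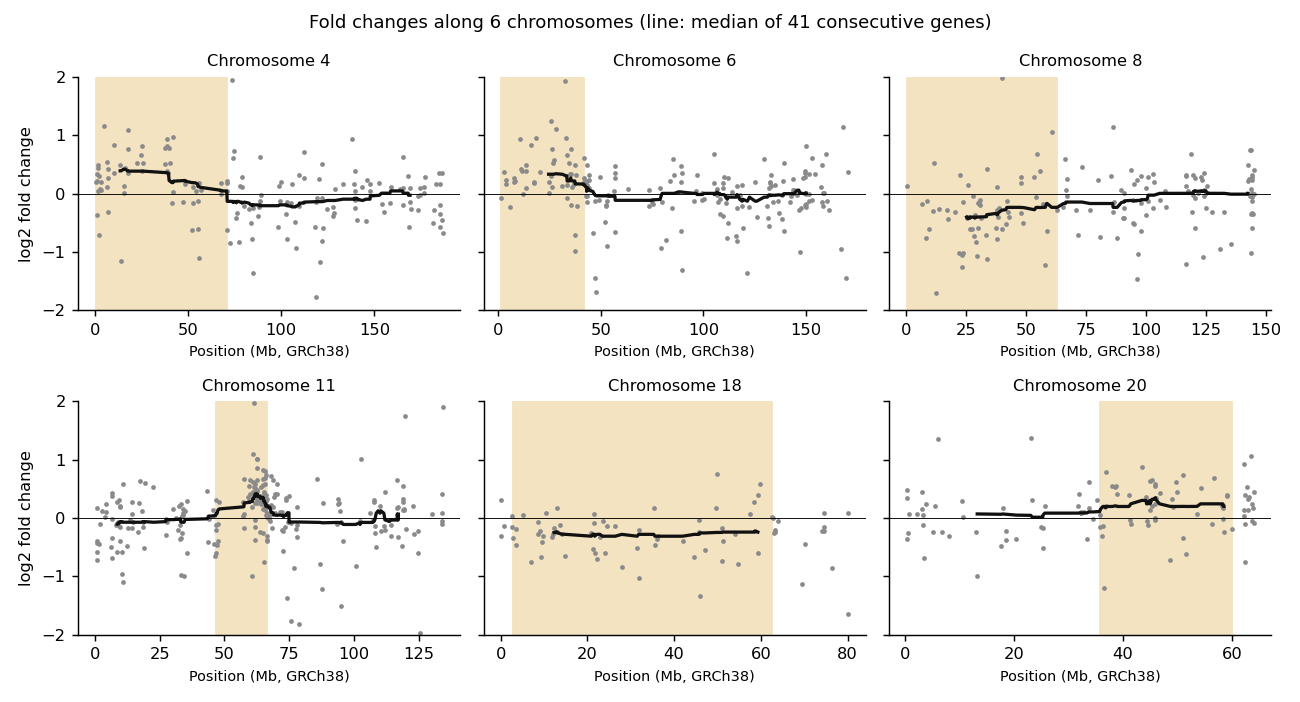
Log2 fold change, knockout over EGFR+vIII (vertical axis, shown from -2 to 2, with genes beyond left out), along 6 chromosomes (horizontal axis, Mb) for genes with a base mean of at least 100 in the authors' deposited table. Points are genes, lines are medians of 41 consecutive genes, and shading marks the 6 regions, from a median of -0.34 on chromosome 8 to 0.29 on chromosomes 6 and 11.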

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

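The alternatives relative to neighbouring genes, corrected for gene span and restricted to genes with 1 accession were chosen after seeing the data. Against 2417 accessions called, 446 were called when a change of more than 1.5-fold was tested, 893 with an empirical null, whose Wald scores had a central spread 1.75 times that of the theory, and 666 with an added 2-fold minimum. The other 6 settings gave 1829 to 2431 calls. Against 11 lists called, 5 passed when ranked by log2 fold change and 5 at a base mean of at least 100, and the other 6 settings gave 8 to 12, with 9 higher and 3 lower by ranks; the cause was not tested. NF-kB genes, interferon-stimulated genes and matrix genes passed in all 8 alternatives. Chemokines passed in the 7 alternatives run for them. They were not tested at a base mean of at least 100, which fewer than 5 of their members reached. At that minimum 20 of the 26 lists were tested, so whether the chemokine call holds there is unknown. The direction given by the set test turned, while the median kept its sign and none was called, for cholesterol synthesis by fold change ranking (median 0.042) and by gene span (0.052), neural stem markers by ranks (0.018), MHC class I by gene span (0.11) and inflammatory cytokines by random lists (-0.048). VWF (-0.033) and NEFM (0.23), called in no setting, changed sign relative to neighbours; the cause was not tested. No called list or named gene reversed, but of 123 called named genes 65 lost the call in the test of a 1.5-fold change, 42 with the empirical null, and 6 each when adjusted over every accession and relative to neighbours. Lists gained a call by ranks (4), among genes with 1 accession (1) and against random lists (1). The alternatives set for TLR2 and those set for values per library (leaving out replicates, another normalization, DESeq2 in place of edgeR, other pseudocounts and no filter on low values) were not run, since TLR2 has no fold change and the table holds no value per library, and other splits of the 6 libraries could not be drawn for the same reason. No paired analysis was possible because the table holds no value per library. Few reads on most genes with several accessions limit what can be called among them.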

Other observations

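Tests chosen only after the result was seen were the test of gene order, the far quartile scan, the search on every other gene, the TLR2 test, the test of group order, the leucocyte test, the test relative to neighbouring genes and the tests of gene families. Of 136 gene families formed from symbols, 3 passed the set test, and they partly restate the matrix list, which holds 2 of the 8 ADAMTS and 11 of the 23 collagen genes. ADAMTS proteases had 5 of 8 tested members lower and 1 higher in the authors' deposited table (adjusted p = 0.00122), with a median log2 fold change of -0.89. Integrin alpha chains had 3 of 9 lower and 0 higher (adjusted p = 0.0086), and collagens 9 of 23 lower and 3 higher (adjusted p = 0.0111) in the authors' deposited table. MMP proteases, with 7 of 11 lower and 1 higher in the authors' deposited table, did not pass (adjusted p = 0.118). Complement C3, chosen after its values were seen, rose by 3.30 on the log2 scale of the authors' deposited table. Log2 fold changes had a slope of -0.13 per unit of the decimal logarithm of gene span over 4227 genes (Spearman rho -0.158, across genes, which are not independent replicates). Of 2065 accessions with a base mean of at least 1000, 26 had an SE above 0.3 in the authors' deposited table, against a median of 0.09, among them NCL (0.33), RPL24 (0.37) and PNN (0.36), chosen after their values were seen.

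Genes with several accessions are mostly listed at or near 0, TLR2 among them. Lack of expression is argued against by ribosomal protein genes, of which 84.8% of those with several accessions lay below a base mean of 100. Loss of reads shared by overlapping accessions is a candidate explanation: 28 of 36 ribosomal protein genes with 1 accession reached a base mean of 100 and 7 of 46 with several did (Fisher's exact test, two-sided, p = 9.93e-09). Whether TLR2 mRNA was absent cannot be told apart from this loss, since all 8 of its accessions overlap and are at 0. No other biological explanation was tested.

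Runs of neighbouring genes shifted together in 6 regions. Chance order of genes is argued against by a permutation test of gene positions (p = 0.002). A few strongly regulated genes within each run are argued against in 5 of 6 regions. There the running far quartile (the lower quartile where genes rose and the upper where they fell) passed the limit of 95% of permutations (largest shift, permutation p = 0.001). This scan used the same fold changes that picked the regions, so it is not independent of them. On chromosome 20 the far quartile did not pass (0.269 against 0.334), so a few strong genes cannot be told apart there. Of the 48 genes of that region, 23 were called higher and 5 lower. Gain or loss of chromosome segments in the cells of 1 group cannot be told apart either: a search on every other gene, meant to leave the rest for measurement, found 0 regions, with a largest shift of 0.42 against a permutation limit of 0.441. Regional control of transcription also stays open, and the knockout itself as the source was not tested.

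Chemokine and interferon-stimulated genes were higher in the knockout. Regional shifts are argued against, since relative to neighbouring genes both lists passed, with a larger adjusted p of 2.04e-05. Leucocyte RNA as the main source could not be decided from 26 abundant leucocyte genes with 1 accession, 11 of them at 0. The upper quartile of their gain in normalized reads in the knockout was 3.83, against a median gain of 134 for the 35 tested genes of both lists. The difference was -131 (95% bootstrap interval -322 to -26.6), computed from the authors' deposited table. The leucocyte side kept genes at 0, whereas both lists kept tested genes only, which favours this outcome. The values show only that most of these leucocyte genes gained few reads. This measure followed a test on 3 markers that had decided nothing. It also followed a share of genes called higher that hung on its base (5 of 26 genes, or 5 of the 10 tested). Leucocyte RNA stays open. The 5 genes called higher were S100A9 (2.19), LAPTM5 (3.92), EVI2B (0.99), CSTA (0.85) and RAC2 (0.42, at a base mean of 4086). The 2 called lower were LCP1 (-0.38) and RGS2 (-0.68), by log2 fold changes of the authors' deposited table. These genes were chosen after their values were seen. A reversed order of the groups cannot be told apart, since 0 TLR2 accessions have a fold change, and an effect of the TLR2 knockout or of clonal differences between the cells stays open and untested.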
